A study of Rattus norvegicus with 6 samples.

How the data were processed

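The series holds 6 one-colour arrays of islet total RNA, 3 from Wistar and 3 from GK rats aged 3 months. Per the labels' protocols, RNA was labelled with Cy3 at the 3' end by RNA ligase. Per the file headers, arrays were read with Agilent Feature Extraction 11.0.1.1. Each deposited scanner file holds spot intensity values for 42734 spots, of which 1417 are controls. The processed signal intensity is background-subtracted within the array and not normalized between arrays, per the file headers and the values. The deposited matrix holds log2 values made by the authors for 18419 piRNA probes, each well above background on at least 1 array. The columns of that matrix share their median (3.94 to 3.95) and have a lowest value per array, so they look quantile-like, and the method is not given in the sources used here. Its Spearman correlation with the scanner values of the same array was between 0.990 and 1.00. The deposited comparison table gives the authors' fold (a ratio) and an unpaired t-test p-value for GK against Wistar, per the file header.

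The 39886 non-control probes comprise 39727 piRNA probes with 1 spot each and 159 others with 10 spots each. The others are 88 probes for rat transcripts, 11 for mammalian miRNAs, 27 for miRNAs of worms, plants and viruses, 12 tiles of accession K00784 and 21 without a name in the files. Names of 61 of the 88 transcript probes (38 genes) came from RefSeq accessions of the rat assembly GRCr8. The strand of these probes is not given in the sources used here. No spot was saturated.

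The values tested were log2 of the processed signal minus each array's 75th percentile. Under 50% of probes were detected, so the percentile was taken over the 7795 probes well above background on all 6 arrays. Spots of a probe were averaged after outlier flags were left out. Probes well above background on at least 3 of the 6 arrays were tested, 11407 in all (11314 piRNAs). The fit was lmFit and eBayes of limma 3.58.1 in R 4.3.3, with strain as the only term, Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p without another name come from this limma fit. A probe not well above background on any array of a strain has only a bound there. Its fold is the brighter mean against the mean of, per array, the higher of its own signal and the lowest signal among probes well above background. The fit tested the measured signals, so an adjusted p given beside such a bound does not belong to the bound.

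Signal over background limits these arrays. The median signal over all probes was 3.41, 2.61 and 2.87 on the Wistar arrays and 3.11, 7.87 and 2.43 on the GK arrays, with GK 2 standing apart. The median SD between arrays of a strain was 0.36 in GK and 0.34 in Wistar on the log2 scale. Correlations between arrays across 11358 probes ran from 0.873 to 0.969, and no pair of arrays was duplicated. GK 1 correlated at 0.959, 0.968 and 0.924 with Wistar 1, 2 and 3, which lay on its slide. With GK 2 and GK 3, on the other slide, GK 1 correlated at 0.923 and 0.945. The number of arrays limits the precision. In 20 sets of simulated data of 11358 probes, limma at an adjusted p of 0.05 called 0% of probes changed 1.5-fold, 0% of those changed 2-fold and 1.74% of those changed 4-fold. The looser criterion of an unadjusted p under 0.05 and a fold of at least 1.5 took 30.3%, 69.3% and 93.6% of them, and 4.87% of unchanged probes. The simulated noise was independent between probes and held no slide effect. The 4.87% is therefore not the chance rate of the real arrays.

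The named probes were chosen by a rule fixed before the data were examined. It took the 12 smallest p in each direction (filled from the looser criterion where fewer than 12 passed), the 2 brightest piRNAs of each strain and the 2 piRNAs remembered from the study. It also took up to 3 probes per direction that were well above background on all arrays of one strain and none of the other. Processing alternatives were fixed at the same time, except the fits within slide 1 and over piRNA probes only, which were chosen after seeing the data. The planned groups of piRNAs by location, annotation and sequence were not analysed here, because coordinates and sequences were not used. None of the listed marker miRNAs of other pancreatic cell types was among the probes, so the makeup of the preparations was not tested. The scanner files give median in place of mean spot signals, so normexp used the median.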

Results

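The arrays measured short RNAs in pancreatic islets of 2 rat strains at 3 months of age. Wistar rats served as the control strain, and Goto-Kakizaki (GK) rats are a non-obese model of type 2 diabetes bred from Wistar stock. PIWI-interacting RNAs (piRNAs) are small RNAs best known from the germline, where they bind PIWI proteins and silence transposons. Islet RNA of 3 Wistar and 3 GK samples was hybridised, 1 sample per array, to 39727 piRNA probes and 159 other probes. The labels state that islet RNA was extracted individually. All 3 Wistar arrays and GK 1 lay on slide 1, and GK 2 and GK 3 lay on slide 2, so strain and slide overlapped in part.

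The first question was how many piRNA probes gave a signal in the islets of each strain. On the Wistar arrays 9699, 11210 and 12101 piRNA probes were well above background, and on the GK arrays 11721, 14373 and 10553. Over the piRNA probes the mean count was 12216 ± 1957 in GK (SD, n = 3) and 11003 ± 1214 in Wistar (SD, n = 3). The difference did not pass a two-sided exact permutation test (p = 0.5, where the smallest p for 3 against 3 is 0.1). Within slide 1 the count of piRNA probes on GK 1, 11721, lay between the counts of Wistar 2 and Wistar 3, and slide 2 held GK samples only. In total 7721 piRNA probes (19.4%) were well above background on all 6 arrays and 21267 on none. The call alone does not show that the named piRNA was present. Of 27 probes for miRNAs of worms, plants and viruses, 8 met it on all 6 arrays.

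**Figure D1:**
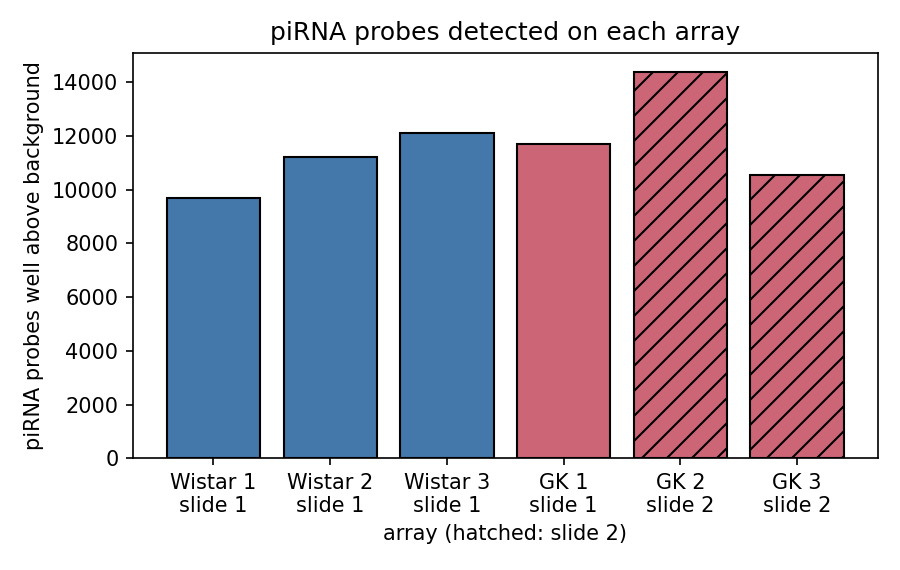
Number of piRNA probes well above background (vertical axis) on each of the 6 arrays, coloured by strain, with the slide 2 arrays hatched. The counts run from 9699 on Wistar 1 to 14373 on GK 2, and those of the strains overlap.

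The same probes gave the brightest piRNA signals in both strains. The probe for DQ610113 came first in each, with a scaled log2 signal of 10.56 ± 0.18 in GK (SD, n = 3) and 10.42 ± 0.03 in Wistar (SD, n = 3). DQ762484 came next, at 10.05 ± 0.29 in GK and 9.84 ± 0.06 in Wistar. Their log2 differences between the strains were 0.14 (SE 0.23) and 0.21 (SE 0.25), with adjusted p of 0.787 and 0.711 in the limma fit. Leaving out the scaling moves each probe measured on all arrays by the same -0.38, which puts these small differences at -0.24 for DQ610113 and -0.18 for DQ762484. Brightness alone does not identify the sequence. The probes for mcmv-miR-m01-1, a virus miRNA, and ppt-miR535a, a plant miRNA, were brighter than 99.6% and 99.4% of piRNA probes.

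The main comparison asked which piRNAs differ between GK and Wistar islets. Of 11407 tested probes, 5 passed an adjusted p of 0.05 in the limma fit. DQ605573, DQ766349, DQ739134 and DQ603001 rose in GK islets. These 4 piRNAs were well above background on all 3 GK arrays and on no Wistar array, so their Wistar level is a bound. DQ605573 was at least 5.29-fold higher, DQ766349 at least 3.26-fold, DQ739134 at least 4.80-fold and DQ603001 at least 4.76-fold. These bounds were not tested. The limma fit took the measured signals, with log2 differences of 4.36 for DQ605573 (adjusted p = 0.0233) and 4.03 for DQ766349 (0.0233). In the same fit they were 3.32 for DQ739134 (0.0247) and 3.66 for DQ603001 (0.0311). DQ728459 fell in GK islets, with a log2 difference of -2.35 (SE 0.23, adjusted p = 0.0354), or 5.11-fold lower. It was well above background on all 3 Wistar arrays and on 1 of the 3 GK arrays. With normexp background correction the differences were smaller and 3 of the 5 missed the threshold. The log2 differences were then 1.06 for DQ605573 (adjusted p = 0.0393), 0.96 for DQ766349 (0.0393), 0.91 for DQ739134 (0.0515), 0.89 for DQ603001 (0.0758) and -0.55 for DQ728459 (0.20), so the bounds above hold for the processed signal only.

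These 5 piRNAs were chosen on all 6 arrays, so their values by slide are not independent of that choice. Within slide 1, GK 1 was at least 6.62-fold above the Wistar arrays for DQ605573, 4.82-fold for DQ766349, 5.79-fold for DQ739134 and 4.02-fold for DQ603001. GK 2 and GK 3 together were at least 4.73-fold, 2.68-fold, 4.36-fold and 5.18-fold above them for the same piRNAs. For DQ728459 the log2 difference from the Wistar mean was -2.17 on GK 1 and -2.45 on GK 2 and GK 3. As slide 2 holds GK samples only, the fit with the slide as a block compares GK 1 alone with the Wistar arrays, and the lone array is assumed to vary like the others. None of the 5 passed in it, where limma's adjusted p was 0.251 for DQ605573, 0.174 for DQ766349, 0.261 for DQ739134, 0.414 for DQ603001 and 0.407 for DQ728459. Within slide 1 alone, where a single GK array stands against 3 Wistar arrays, 0 probes passed the limma fit and 390 had an unadjusted p under 0.05. Leaving out any one of the 3 Wistar arrays, GK 2 or GK 3 left 0 probes past the adjusted threshold, whereas 21 passed without GK 1. Without GK 1 every GK array lies on slide 2 and every Wistar array on slide 1, so that fit cannot tell strain from slide.

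**Figure D2:**
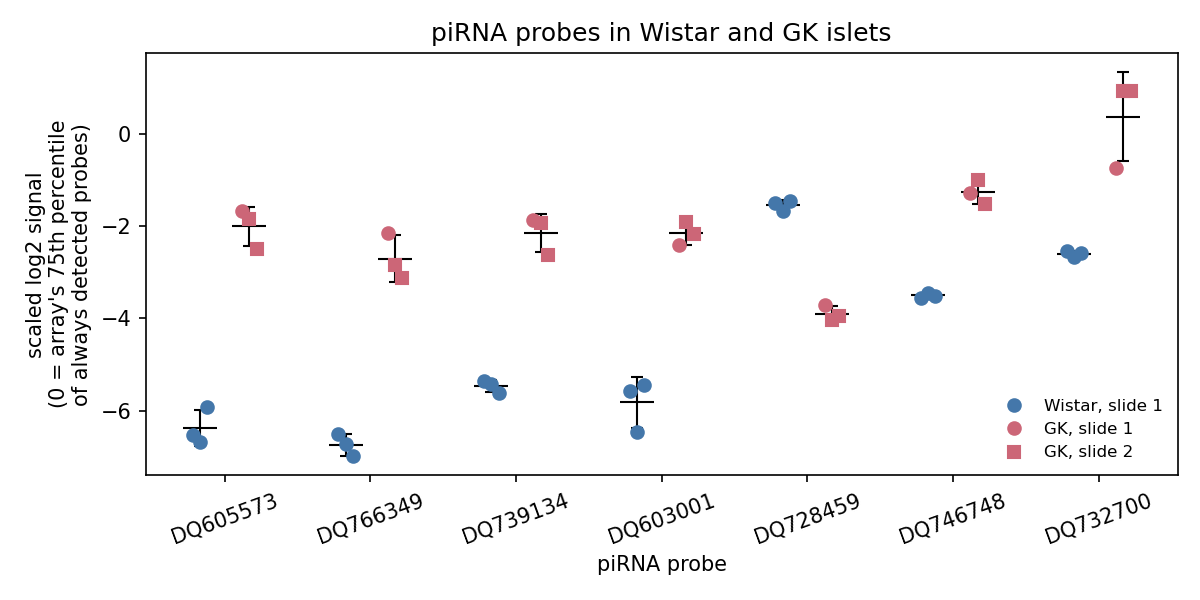
Scaled log2 signal (vertical axis) of 7 piRNA probes on each array, with circles for slide 1 and squares for slide 2; black bars are the mean ± SD of the 3 arrays of a strain. DQ605573, DQ766349, DQ739134 and DQ603001 were not well above background on any Wistar array, and GK 1 sits with the GK arrays of slide 2 except for DQ732700, where it lies at -0.74 against 0.92 and 0.93.

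DQ746748 and DQ732700 were named before the data were examined, as piRNAs the study is remembered to have followed up. The study chose them on these same samples, so they are not independent evidence. DQ746748 was 4.71-fold higher in GK islets, with a log2 difference of 2.24 (SE 0.24). DQ732700 was 7.83-fold higher, with a log2 difference of 2.97 (SE 0.47). Both were well above background on all 6 arrays. Adjusted over the list alone, 2 of 2 passed in the limma fit, with adjusted p of 6.02e-05 for DQ746748 and 0.000358 for DQ732700. Over all tested probes neither passed, at 0.0528 and 0.146. DQ746748 passed over all tested probes with normexp (0.0468), with outlier spots kept (0.0496), with trend and robust eBayes (0.0326) and among probes detected on all 6 arrays (0.0464). It missed with quantile normalization (0.123), the percentile over all non-control probes (0.115), no scaling (0.141) and the authors' matrix values (0.0964). It also missed without the filter on dim probes (0.281), in an unmoderated linear model (0.287) and with the replicate number as a block (0.216). Within slide 1 GK 1 exceeded the Wistar mean by 2.22 for DQ746748 and 1.86 for DQ732700, and GK 2 and GK 3 exceeded it by 2.24 and 3.53. With the slide as a block, which again compares GK 1 alone with the Wistar arrays, the adjusted p was 0.422 for each over all tested probes, and the larger of the 2 over the list alone was 0.000692. With normexp the log2 differences were 1.02 for DQ746748 and 1.79 for DQ732700.

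Of the 12 probes named for higher GK values, 6 piRNAs missed the adjusted threshold and were not well above background on any Wistar array. DQ750951 was at least 3.32-fold higher in GK (adjusted p = 0.0560 in the limma fit), DQ623728 at least 2.58-fold, DQ612238 at least 2.21-fold, DQ760570 at least 2.01-fold, DQ618392 at least 1.85-fold and DQ737219 at least 1.85-fold. Their adjusted p lay between 0.0560 and 0.0578 in the limma fit of the measured signals, and the bounds were not tested. With normexp their log2 differences were smaller than these bounds, at 0.87, 0.79, 0.72, 0.70, 0.70 and 0.73 in the same order, and none passed. None passed with quantile normalization either. With the percentile over all non-control probes DQ760570 (adjusted p = 0.0142 in the limma fit), DQ623728 (0.0352) and DQ737219 (0.0355) passed and the others did not. The probe A_44_P288091 for P2rx2, an ATP-gated ion channel, was well above background on all arrays and had a log2 difference of 3.19 (SE 0.39, adjusted p = 0.0586). It passed with normexp, at 1.55 (adjusted p = 0.0181), and with trend and robust eBayes of limma (adjusted p = 0.0471). DQ611669, detected on all GK arrays and no Wistar array, was at least 5.05-fold higher in GK. Its measured log2 difference was 3.35 (adjusted p = 0.115 in the limma fit), and 0.97 under normexp. By slide, DQ611669 was at least 2.44-fold higher on GK 1 and 7.26-fold on GK 2 and GK 3. It passed in the limma fit with the percentile over all non-control probes (adjusted p = 0.0355). It also passed without GK 1 (0.0474), a fit in which strain and slide coincide.

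Other piRNAs had lower GK values and missed the threshold. DQ748190 was well above background on every Wistar array and on no GK array, and was at least 13.4-fold lower in GK. Its measured log2 difference was -4.21 (adjusted p = 0.0528 in the limma fit), against -1.40 with normexp (adjusted p = 0.109). DQ748190 passed with the percentile over all non-control probes (0.00819), without scaling (0.0357), with outlier spots kept (0.0496) and with trend and robust eBayes (0.0309). It missed with quantile normalization (0.206), the authors' matrix values (0.0697) and no filter on dim probes (0.281). It also missed in an unmoderated linear model (0.402) and with the replicate number as a block (0.198). DQ765092 had a log2 difference of -2.63 (SE 0.29, adjusted p = 0.0540), DQ728575 of -3.40 (SE 0.45, 0.0841), DQ745550 of -2.64 (SE 0.37, 0.0956) and DQ749105 of -1.86 (SE 0.27, 0.111). DQ756757 and DQ763038 had log2 differences of -2.65 and -1.34, and for DQ756757 the value was -1.64 on GK 1 within slide 1 and -3.15 on GK 2 and GK 3. For DQ763038 the difference shrank to -0.15 with normexp (adjusted p = 0.443 in the limma fit). DQ747341 and DQ737664 had differences of -2.79 and -1.80, resting on 1 and 2 Wistar arrays after outlier spots were left out. With normexp 7 of these piRNAs passed the adjusted threshold, with log2 differences of -2.29 for DQ728575, -2.07 for DQ756757, -1.98 for DQ747341, -1.64 for DQ745550, -1.45 for DQ749105, -1.39 for DQ737664 and -1.38 for DQ765092. DQ747687, DQ749828, DQ619820 and DQ758053 were not well above background on any GK array, and were at least 1.22-fold, 1.18-fold, 3.07-fold and 2.31-fold lower there. With normexp these 4 differences were -0.00029 for DQ747687, 0.13 for DQ749828, -0.31 for DQ619820 and -0.06 for DQ758053, so they rest on the processed signal.

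On all 3 arrays of one strain and no array of the other, 64 probes were well above background in GK (62 of them piRNAs) and 44 piRNAs in Wistar. Other choices of 3 of the 6 arrays gave up to 298 such probes.

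At an unadjusted p under 0.05 and a fold of at least 1.5, 1218 probes differed, 902 higher and 316 lower in GK. The direction of this larger set turned with the scaling between arrays. Quantile normalization gave 394 higher and 604 lower, the percentile over all non-control probes 167 and 1099, no scaling 235 and 1020, and the authors' matrix values 404 and 715. The percentile over all non-control probes and no scaling each move every probe measured on all arrays by one amount, -0.48 and -0.38, so their turned counts follow by construction. The median log2 difference over tested probes was 0.17, against -0.10 with quantile normalization and -0.31 with the percentile over all non-control probes. With the slide as a block 417 probes met this criterion, 295 higher and 122 lower, and within slide 1 there were 390, 277 higher and 113 lower. The count was 597 without GK 2, 655 without GK 3, 725 without Wistar 2 and 2516 without GK 1, where strain and slide coincide.

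**Figure D3:**
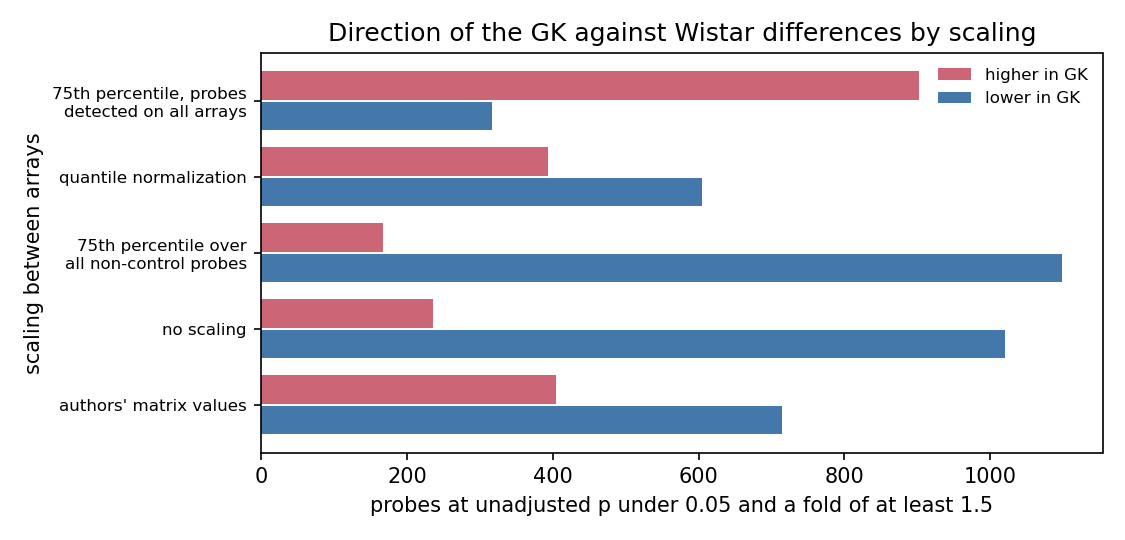
Number of probes at an unadjusted p under 0.05 and a fold of at least 1.5 (horizontal axis), split into higher and lower in GK, for 5 ways of scaling between arrays (vertical axis). Higher probes outnumbered lower ones, 902 to 316, only with the 75th percentile over probes detected on all arrays.

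The authors' deposited table lists 347 piRNAs at a fold of at least 2 and an unadjusted p of at most 0.05, 128 higher and 219 lower in GK. Of these, 270 were tested here, all 270 with the same direction, and 228 had an unadjusted p under 0.05. These were all 102 of the tested piRNAs listed as higher and 126 of the 168 listed as lower, and with quantile normalization 269 of the 270. All 5 piRNAs past the adjusted threshold are listed. The authors drew the list from these same arrays, so this overlap and the shared directions are not independent evidence. In the authors' deposited table DQ605573 has a fold of 8.39 upward, DQ766349 4.68, DQ739134 7.12, DQ603001 7.19, DQ746748 3.94 and DQ732700 7.23. DQ728459 has a downward fold of 6.74 and DQ748190 of 19.5 in the authors' deposited table. The methods' t-test, rerun on the deposited matrix, gave the same 347 piRNAs. After Benjamini-Hochberg adjustment 1 of 18419 remained, DQ737219, whose 3 Wistar values all sit at the lowest value of their array. limma on all 18419 probes of this matrix left 0, with a smallest adjusted p of 0.0847. On the 11315 of them well above background on at least 3 arrays, which is not exactly the set of 11314 piRNAs fitted here, it left 2. In total 1141 of the 18419 had an unadjusted p of at most 0.05, where 921 would arise by chance if the slide had no effect. Of the 128 piRNAs listed as higher, 56 were well above background on no Wistar array, and of the 219 listed as lower, 77 on no GK array. The list holds more lower than higher piRNAs, whereas the percentile over probes detected on all arrays gave the opposite balance.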

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

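Of the tests in this part, those on the array splits, on scaling, on dim probes and on probes for foreign miRNAs were chosen after the result was seen, and the held-out array tests before.

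A signal in probes outside the piRNA measurement was picked out. Of 27 probes for miRNAs of worms, plants and viruses, 8 were well above background on all 6 arrays. The mean signal was 6705 for mcmv-miR-m01-1 and 4952 for ppt-miR535a. RNA of a single foreign organism is argued against, since the 8 probes name 6 organisms. Hybridisation that is not specific to the named sequence may account for them, as 29.6% of them were detected on all 6 arrays (95% interval 13.8% to 50.2%), against 19.4% of piRNA probes (Fisher's exact test, two-sided p = 0.219). No biological explanation was tested.

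Strain and slide overlap in part, so GK 1, the GK array on slide 1, was set against a held-out Wistar array on probes chosen from GK 2, GK 3 and the other Wistar arrays. GK 1 covered a median share of 0.25, 0.23 and 0.28 of the GK 2 and GK 3 shift, and the held-out Wistar array 0.23, 0.04 and 0.27, for Wistar 1, 2 and 3 held out. Strain as the whole cause stays open. The rule set beforehand counted a GK 1 share under 0.8 in each of the 3 choices against it. The largest GK 1 share was 0.283, so that rule was met. The rule took no account of choosing probes on GK 2 and GK 3, which exaggerates their shift. As GK 1 is also a single array, the rule was not applied. The slide as the whole cause stays open too, as the GK 1 share exceeded the held-out share by only 0.00775 with Wistar 3 held out and by 0.194 with Wistar 2. The share of probes on the side of GK 2 and GK 3 was higher for GK 1 in all 3 choices, at 74.4%, 72.4% and 78.0% against 67.4%, 56.8% and 68.5% for the held-out array, and single arrays do not settle it.

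Higher probes outnumbered lower ones in GK, 902 against 316. The scaling between arrays stays open: the ratio of higher to lower was 0.152 with the percentile over all probes, but that scaling moves the log2 difference of each probe measured on all arrays by the same -0.48, so the turn follows by construction. Quantile normalization gave a ratio of 0.652 and the authors' matrix 0.565, and these do not move every probe alike, but they equalise the arrays' medians and so do not decide it. The background of dim probes stays open too. The ratio was 2.75 among probes well above background on all 6 arrays, yet 1.31 in the brightest 2852 tested probes (161 higher, 123 lower) against 3.88 in the dimmest 2852 (260 and 67). A strain difference in the overall level of these RNAs stays open and was not tested.

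The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. At the adjusted threshold the real split gave 5 probes and the highest other split 0, and 1 of the 10 splits reached the real value. At the looser criterion the real split gave 1218 and the highest other 1399, so 2 of the 10 reached the real value. That other split set GK 2, GK 3 and Wistar 3 against the rest and so followed the slides except for Wistar 3, and with the slide as a block the real count was 417.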

How the results depend on the processing

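The fits within slide 1 and over piRNA probes only were chosen after seeing the data. The 5 piRNAs past the adjusted threshold, chosen on these same arrays, kept their direction under each alternative that tested them. The number of probes past it was 15 with normexp (7 higher and 8 lower, with 2 of the 5 still among them) and 14 with the percentile over all non-control probes (with all 5). It was 8 with the median of all spots and outlier spots kept (with all 5) and 8 with trend and robust eBayes (with 4 of the 5). It was 6 without scaling (with 4 of the 5) and 20 at an adjusted p under 0.1. It was 2 with the authors' matrix values over 11315 probes (2 of the 5) and 2 with detection on all 6 arrays. It was 0 with quantile normalization (1005 at an unadjusted p under 0.05), no filter (2510), the unmoderated model (1026), the slide as a block, which compares GK 1 alone with the Wistar arrays (417 at an unadjusted p under 0.05) and within slide 1 (390). Leaving out 1 array gave 0 to 21: 21 without GK 1, where strain and slide coincide, and 0 without any of the others. The looser count of 1218 became 613 with normexp (where 2352 had an unadjusted p under 0.05 at any fold), 2510 with no filter, 668 with the unmoderated model, 417 with the slide as a block, 390 within slide 1 and 680 at a fold of 2. It ran from 597 without GK 2 to 2516 without GK 1, with 655 without GK 3 and 725 without Wistar 2. The median difference was -0.10 with quantile normalization, -0.31 with the percentile over all probes, -0.22 without scaling, -0.10 with the authors' matrix values and 0.39 with no filter. Leaving out 1 array moved it between 0.11 and 0.21. The cause was not tested, except that detection on all 6 arrays left out all 5 piRNAs by construction, and that the normexp offset of 50 draws dim signals together.

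Of 548 values of named probes under alternatives, 540 kept their direction or were 0. These values are 30 named probes counted again under each alternative that fitted them. Most were chosen for a small p on these same arrays, so a kept direction was likely. Of the named probes that missed the adjusted threshold, 9 passed with normexp, 8 with the percentile over all probes and 4 with trend and robust eBayes. With the median of all spots and outlier spots kept 3 passed, without scaling 2, with detection on all 6 arrays 2 and without GK 1 2. DQ749828 became 0.13 with normexp. DQ762484 became -0.00013 with quantile normalization and -0.0832 both with the slide as a block and within slide 1. With the percentile over all probes DQ610113 was -0.34 and DQ762484 -0.27, and without scaling they were -0.24 and -0.18. DQ746748 and DQ732700 stayed past the threshold over the list alone in each alternative run. The study chose both on these same samples, so this is not independent evidence. Over all tested probes neither passed in the main limma fit, with adjusted p of 0.0528 and 0.146.

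The replicate numbers do not pair the samples: deviations of same-numbered arrays correlated at -0.03, 0.04 and 0.04. The fit with the replicate block gave 0 calls and 1273 probes at an unadjusted p under 0.05. Group tests by location, annotation and sequence were not run.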

Other observations

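The tests on neighbouring accessions were chosen after the correlation was seen, except the test on array position.

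Of 88 probes for rat transcripts, 70 were tested and 0 passed the adjusted threshold in the limma fit, with 15 higher and 1 lower at an unadjusted p under 0.05 and a fold of at least 1.5. The 3 probes for B2m, the light chain of MHC class I, had log2 differences of 1.75 (SE 0.25), 0.94 (SE 0.29) and 0.51 (SE 0.32) in GK. The split of higher and lower was 13 and 2 with quantile normalization, 7 and 3 with the percentile over all non-control probes and 9 and 3 without scaling. Each B2m probe stayed above 0 under these scalings, the lowest value being 0.03. The probes for Gapdh (1.26, 0.75 and 0.59) and Rplp1 (0.42, 0.38 and 0.25) were also above 0 in the main fit, and those for Sdha below 0 (-0.27, -0.59 and -0.21). Enpp1, an ectonucleotide pyrophosphatase, was at least 3.83-fold higher in GK, being well above background on no Wistar array. Napepld had a log2 difference of 2.16 and Pdk3, a kinase of pyruvate dehydrogenase, of 1.57, while Cdh2, which encodes N-cadherin, had -0.97.

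Wistar 3 was the lowest of the 6 arrays for 23 of these 70 transcript probes and for 26.2% of tested piRNA probes, and Wistar 2 for 18 and for 11.7%. Of the 41 with names that start with A_, Wistar 3 was lowest for 17, Wistar 2 for 14, Wistar 1 for 3 and the GK arrays for 1, 4 and 2. The probes for P2rx2, Enpp1, Napepld, Pdk3 and Cdh2 are of this kind, and Wistar 1 was the highest Wistar array for each. For the Ldha probe A_44_P210461 Wistar 3 had a scaled log2 signal of -6.30, against -1.04 and -2.23 on the other Wistar arrays and -0.19 to 0.48 on the GK arrays. Another Ldha probe, CUST_18_PI422140147, had 4.34 on Wistar 3, 4.85 and 4.67 on the other Wistar arrays and 4.59 to 5.26 on the GK arrays. The third tested Ldha probe, CUST_17_PI422140147, had -5.94 on Wistar 3, -4.48 and -3.87 on the other Wistar arrays and -4.06 to -3.17 on the GK arrays.

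piRNAs with consecutive accession numbers may share sequence or a source. Across 2468 pairs of consecutive accessions, the log2 differences between the strains correlated at r = 0.130 (permutation p = 1e-04, the smallest that 10000 permutations can give). The correlation is across probes, which are not independent replicates. It was 0.00 for accessions 2 apart. In the 2443 pairs of spots more than 10 rows or 10 columns apart r was 0.128. These are nearly all of the 2468 pairs, so r could hardly change and the test does not decide on position on the array.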
